A study of Homo sapiens with 12 samples.

How the data were processed

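RNA-seq was measured in 12 libraries of 2 human cell lines, in 6 groups of 2 taken from the labels. Per the labels' protocols, RNA was purified on columns, treated with DNase, depleted of ribosomal RNA and made into stranded libraries, in the same way for all samples. The submitters' processing notes name STAR 2.7.10b, SAMtools 1.17 and bcl2fastq 2.20. All deposited values used here were raw counts. For U2OS batch 1 the authors deposited counts in the layout of STAR's gene counts, with 231134 transcripts as features and no annotation given in the sources used here. Reads on more than 1 transcript were not assigned, which was 84.9% to 85.2% of exonic reads, so genes with many transcripts lost most of their reads. For WI38 and U2OS batch 2, counts per gene came from featureCounts 2.0.4 with strand setting 2 and the NCBI RefSeq annotation of T2T-CHM13v2.0, per the file headers. WI38 was counted from read 1. In U2OS batch 2 both ends of a pair were counted, per the file headers, and 75.8% to 78.1% of counts from 1 to 20 were even, against 39.9% to 42.1% elsewhere. Such counts overstate the depth. The treatment label of the siEZH2 libraries names only control or siORCA, so their group came from the titles.

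The sense column of U2OS batch 1 was summed over transcripts to 60293 genes by the gene part of the transcript name. Rows that name no gene (2596, with 0.663% of counts) and the unassigned totals were left out. The other tables held 42933 genes, 27363 were in both, and 712 and 92 older symbols were renamed. Transcript classes of LRWD1 came from another annotation and were matched by name. No library differed from another by sampling noise alone. Total counts ran from 2978005 to 136867944, and with 2 libraries per group precision is set by the spread between them as much as by depth.

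Each comparison used its own 4 libraries: edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr (minimum count 10, minimum total 15) and the quasi-likelihood test, 2-sided, with Benjamini-Hochberg adjusted p under 0.05. Standard errors were derived from the same fit. The 2 interactions were fitted over the 8 libraries of both experiments. The 32 gene lists were fixed before the data were examined. Those with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry. The version with an estimated correlation rests on the few degrees of freedom left by the libraries. For extracellular matrix genes in U2OS siORCA, camera's unadjusted p went from 0.00280 to 0.0780 at an estimated correlation of −0.008. A call lost there does not by itself show that correlation between members was the reason. Estimates differed between lists in that comparison, with 0.029 for cholesterol biosynthesis, 0.313 for histones and 0.397 for osteoblast genes. For lists with high estimates, correlation between members may have contributed. The design, named-gene rule and most alternatives were also fixed then. Alternatives were DESeq2 1.42.0 and its size factors, limma-voom, library totals, no filter, a filter of 1 CPM in 2 libraries, a replicate block, a shared fit, an adjusted p under 0.01, a 2-fold minimum and leaving out each library. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

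Named genes were LRWD1 and EZH2, the 10 highest and 10 lowest changes per comparison at 5 CPM or more with separated libraries, up to 4 members of each list by smallest p, up to 5 genes per direction shared by or opposed in a pair of comparisons, and the 5 highest and 5 lowest differences of each interaction. Unnamed loci were left out, and some genes are not reported here. Genes printed were chosen from these after their values were seen, with low counts mostly dropped. EZH1 in U2OS siEZH2, the genes of bone morphogenetic protein signalling given as a group and the RNA polymerase III transcripts were chosen outside the rule after their values were seen.

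The fits were tested on simulated data with 0.5, 1 and 2 log2 changes. Of these, 12.3%, 53.2% and 93.4% were recovered for U2OS siORCA (13498 genes, 3 unchanged genes called), 69.7%, 86.6% and 100% for WI38 siORCA (14589 genes, 7 called) and 24.2%, 46.3% and 84.6% for U2OS siEZH2 (22642 genes, 15 called). For the interaction between lines, 91% of 200 differences of 2 were recovered (15409 genes, 6 called). Only 188, 198 and 198 genes were changed in the simulations of U2OS siORCA, WI38 siORCA and U2OS siEZH2. In the data 827, 6074 and 14149 genes were called, and 1611 for the interaction. The Benjamini-Hochberg threshold is stricter where fewer genes change, so these shares do not estimate what was missed in the data.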

Results

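RNA-seq was carried out in 2 human cell lines, U2OS, an osteosarcoma line, and WI38, a diploid lung fibroblast line. The question put by the submitters was how loss of ORCA affects transcription. ORCA, encoded by LRWD1, binds the origin recognition complex and chromatin, and EZH2 is the catalytic subunit of Polycomb repressive complex PRC2. There were 12 libraries in 6 groups of 2: U2OS control and siORCA (batch 1), WI38 control and siORCA, and U2OS control and siEZH2 (batch 2). Total counts per library were 2978005 to 3560212 in U2OS batch 1, 21392292 to 25724672 in WI38 and 72403244 to 136867944 in U2OS batch 2. Levels are CPM (counts scaled to the library total times its TMM factor, mean ± SD, n = 2 libraries per group). Changes are log2 fold changes with their standard error (SE), with adjusted p-values from edgeR's quasi-likelihood test. Nothing in the labels says that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. One siRNA label was given per target, so off-target effects cannot be told apart from loss of the target.

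LRWD1 (chromosome 7, 103782613 to 103790767, plus strand, T2T-CHM13v2.0) fell in WI38 siORCA, from 18.6 ± 0.815 to 3.48 ± 1.31 CPM. It had 396 and 420 counts in the control libraries and 112 and 54 in the siORCA libraries (log2 fold change −2.39, SE 0.18, adjusted p = 1.81e-07). In U2OS batch 1 it had 30 and 49 counts in control and 39 and 25 in siORCA (log2 fold change −0.38, SE 0.28, adjusted p = 0.546). Of those U2OS counts, 142 lay on LRWD1-205, classed as a retained intron, 1 on a transcript classed for nonsense-mediated decay and 0 on transcripts classed as protein-coding. These classes came from another annotation, matched by transcript name. With no count on a protein-coding transcript, the U2OS batch 1 files do not check the knockdown of LRWD1. EZH2 (chromosome 7, 149989157 to 150066070, minus strand) fell in U2OS siEZH2, with 2809 and 3430 counts in control and 631 and 810 in siEZH2 (log2 fold change −1.55, SE 0.12, adjusted p = 1.74e-05). The headings of the siEZH2 columns differ in the digit after EZH, which can be read as a replicate number or as another target. EZH1 fell too, with 3816 and 4827 counts in control and 1243 and 2001 in these libraries (−0.88, SE 0.08). Both EZH2 and EZH1 had fewer counts in each of these columns than in either control, so the columns did not differ in which gene fell. EZH2 also fell in WI38 siORCA, from 325 and 364 counts to 254 and 213 (log2 fold change −0.65, SE 0.11, adjusted p = 5.11e-04). Without WI38 siORCA replicate 1 that EZH2 value was −0.64 and no longer passed (adjusted p = 0.0528). In U2OS batch 1, EZH2 had 20 and 26 counts in control and 24 and 17 in siORCA (log2 fold change −0.25, SE 0.35, adjusted p = 0.798). EZH2-201, EZH2-202 and EZH2-203 had 0 counts in each of these libraries, where reads on more than 1 transcript were not assigned. So few counts do not settle whether EZH2 changed there. LRWD1 rose in U2OS siEZH2, with 1797 and 2256 counts in control and 1534 and 2777 in siEZH2 (log2 fold change 0.60, SE 0.09, adjusted p = 6.12e-04).

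**Figure D1:**
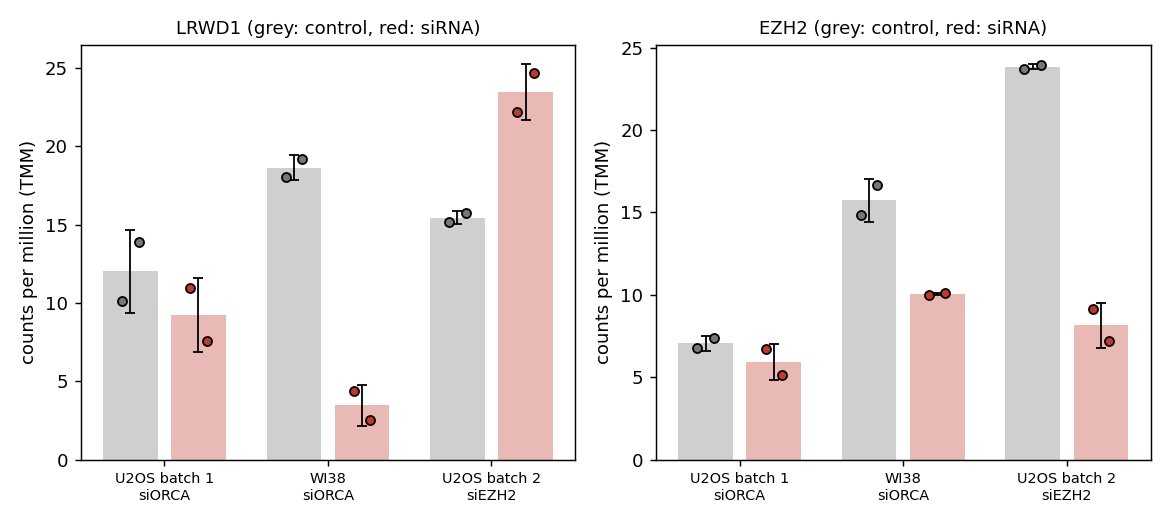
CPM (TMM-scaled, y axis from 0) of LRWD1 (left) and EZH2 (right) in control (grey) and siRNA (red) libraries of the 3 comparisons; points are libraries, bars are means and error bars are the SD of 2 libraries. LRWD1 lay at 18.6 ± 0.815 in WI38 control and 3.48 ± 1.31 in WI38 siORCA, and EZH2 fell in U2OS siEZH2 and WI38 siORCA.

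In U2OS siORCA, F13A1, which encodes the A chain of coagulation factor XIII, fell from 146 ± 7.0 to 21.8 ± 1.24 CPM (log2 fold change −2.73, SE 0.15, adjusted p = 7.20e-15). The membrane mucin gene MUC4 (−2.86, SE 0.23), the tight junction gene CLDN1 (−2.56, SE 0.17), the caveolar gene CAVIN2 (−2.01, SE 0.12), the cytokine gene CSF2 (−2.12, SE 0.22) and EDN1, encoding endothelin-1 (−1.82, SE 0.15), fell too. SOX2, a transcription factor of stem and progenitor cells, rose from 298 ± 14.9 to 707 ± 137 CPM (log2 fold change 1.25, SE 0.12, adjusted p = 2.27e-09). DDIT4, an inhibitor of mTORC1 signalling (1.02, SE 0.10), the neurofilament gene NEFL (0.94, SE 0.11) and CA12, a carbonic anhydrase gene (1.17, SE 0.18), rose as well.

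Among the gene lists in U2OS siORCA, immediate early genes, which respond quickly to growth factors and stress, had 18 tested members, of which 0 rose, 7 fell and 11 did not pass (0 and 10 adjusted over the list alone). Examples were EGR1 (−1.05, SE 0.11), CCN1 (−1.04, SE 0.18), CCN2 (−0.79, SE 0.11) and the phosphatase gene DUSP5 (−0.93, SE 0.13). Camera gave the list an adjusted p = 4.46e-11. That call was lost, at adjusted p = 0.499, with an estimated correlation. Fry called 0 lists in this comparison. Cholesterol biosynthesis had 1 higher and 5 lower of 24 (2 and 9 adjusted over the list alone; adjusted p = 0.00557, and adjusted p = 0.572 with an estimated correlation), with SQLE (−0.57, SE 0.10), FDPS (−0.74, SE 0.16) and CYP51A1 (−0.69, SE 0.17). Inflammatory cytokines and NF-kB targets had 1 higher and 3 lower of 14 (1 and 6 adjusted over the list alone; adjusted p = 0.00557, and adjusted p = 0.572 with an estimated correlation), with CSF2 and LIF (−0.60, SE 0.10). Extracellular matrix genes had 2 higher and 5 lower of 28 (3 and 7 adjusted over the list alone; adjusted p = 0.0120, and adjusted p = 0.572 with an estimated correlation), with the collagen genes COL6A3 (−0.91, SE 0.14) and COL3A1 (−0.50, SE 0.13). Osteoblast genes had 0 higher and 2 lower of 7 (0 and 3 adjusted over the list alone; adjusted p = 0.0120, and adjusted p = 0.572 with an estimated correlation), the members that passed being TNFRSF11B, encoding osteoprotegerin (−1.52, SE 0.16), and BMP2 (−0.47, SE 0.13). Epithelial markers had 0 higher and 1 lower of 5 (0 and 2 adjusted over the list alone; adjusted p = 0.0314, and adjusted p = 0.572 with an estimated correlation), and the 1 that passed was KRT5, at 11, 20, 4 and 2 counts. Replication-dependent histones had 4 higher and 0 lower of 37 (the same adjusted over the list alone; adjusted p = 0.00110, and adjusted p = 0.572 with an estimated correlation), with H4C9 (0.65, SE 0.10) and H2AC15 (0.44, SE 0.11). Clustered protocadherins had 2 higher and 0 lower of 25 (3 and 0 adjusted over the list alone; adjusted p = 0.0112, and adjusted p = 0.572 with an estimated correlation), with PCDHB5 (0.36, SE 0.10) and PCDHB16 (0.50, SE 0.15). Histone and protocadherin genes have near-identical copies, so their single values are uncertain.

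In all, 827 of 14014 genes tested changed in U2OS siORCA, 270 higher and 557 lower, of which 61 and 194 changed at least 2-fold. The integrated stress response list was not called (24 tested, 2 higher and 3 lower, 4 and 6 adjusted over the list alone; adjusted p = 0.780). Its members moved apart, with DDIT4 higher and the amino acid transporter gene SLC7A5 lower (−0.86, SE 0.11). Of the 50 G2/M, 30 licensing and 29 fork genes tested, 0 passed with edgeR, DESeq2 or limma, and 3, 5 and 2 had an unadjusted p under 0.05 with edgeR. The share of counts on ribosomal RNA, mitochondrial ribosomal RNA included, was 1.01% and 0.940% in control and 1.18% and 3.05% in siORCA. The mitochondrial ribosomal RNA MT-RNR1, which is part of that share, was at 810, 516, 5932 and 27001 counts in these libraries. The count of changed genes fell to 444 without control replicate 1, to 280 without control replicate 2 and to 350 with DESeq2, and single calls were lost in the same way. CYP51A1, COL3A1, BMP2, PCDHB5, PCDHB16, KRT5, ID3 and SGK1 did not pass with DESeq2 or without control replicate 2, nor did SQLE without that library, or FDPS and H2AC15 without control replicate 1. HOXB9 did not pass without either control library. About 85% of the exonic reads of these libraries lay on more than 1 transcript and were not counted by the submitters' pipeline, which leaves genes with many transcripts with few counts.

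In WI38 siORCA, the mitotic kinesin gene KIF20A fell from 55.2 ± 2.31 to 20.8 ± 1.28 CPM (log2 fold change −1.40, SE 0.08, adjusted p = 1.59e-08), and CCNA2, encoding cyclin A2, from 44.4 ± 4.20 to 14.5 ± 2.99 (−1.60, SE 0.12, adjusted p = 2.00e-07). CDKN1A, encoding the cyclin-dependent kinase inhibitor p21, rose from 581 ± 4.90 to 1326 ± 58.4 (1.19, SE 0.06, adjusted p = 7.65e-09), and MDM2, encoding the ubiquitin ligase of p53, by 1.05 (SE 0.06). The largest increases by the naming rule included TNFSF18 (3.80, SE 0.33), the deiodinase gene DIO2 (3.49, SE 0.09), TNFSF4 (3.29, SE 0.10), the elastin gene ELN (3.01, SE 0.08) and the oxytocin receptor gene OXTR (2.81, SE 0.08). The largest decreases included PCSK2, a prohormone convertase gene (−4.98, SE 0.20), AGT, encoding angiotensinogen (−4.27, SE 0.23), the growth factor gene BMP5 (−3.81, SE 0.13) and the alcohol dehydrogenase gene ADH1B (−3.74, SE 0.09).

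Of the 57 G2/M mitotic genes tested in WI38, 0 rose, 55 fell and 2 did not pass (the same adjusted over the list alone; adjusted p = 1.68e-28 by camera, but adjusted p = 0.392 with an estimated correlation). They included AURKA (−1.30, SE 0.08), TOP2A (−1.31, SE 0.09) and CCNB1 (−1.17, SE 0.09). Replication-dependent histones fell in 57 of 58 cases (58 adjusted over the list alone; adjusted p = 1.66e-67, and adjusted p = 0.265 with an estimated correlation), including H1-5 (−1.93, SE 0.08) and H2AC12 (−2.49, SE 0.11). Single noncoding RNAs that fell, which were not tested as a list, were RN7SL1 (−2.07, SE 0.16), RMRP (−1.79, SE 0.15), RPPH1 (−2.56, SE 0.23), RN7SK (−1.38, SE 0.14), SCARNA10 (−3.85, SE 0.22) and SNORD17 (−3.63, SE 0.13). The origin recognition and licensing list had 1 member higher and 25 lower of 33 (3 and 26 adjusted over the list alone; adjusted p = 1.87e-06, and adjusted p = 0.414 with an estimated correlation). MCM4 (−0.93, SE 0.08), MCM7 (−0.87, SE 0.07) and CDC6 (−1.24, SE 0.12) fell. Replication fork genes had 0 higher and 28 lower of 38 (2 and 30 adjusted over the list alone; adjusted p = 1.29e-05, and adjusted p = 0.414 with an estimated correlation), among them RRM2 (−1.11, SE 0.10) and TK1 (−1.03, SE 0.11), which make nucleotide precursors. G1/S E2F targets had 0 higher and 28 lower of 33 (0 and 29 adjusted over the list alone; adjusted p = 2.10e-07, and adjusted p = 0.414 with an estimated correlation), with CDK2 (−0.70, SE 0.08). The cohesin, condensin and CTCF list had 3 higher and 11 lower of 27 (4 and 11 adjusted over the list alone; adjusted p = 0.0360, and adjusted p = 0.599 with an estimated correlation), and TOP2A is one of its members.

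The p53 target list in WI38 had 31 members higher, 1 lower and 3 that did not pass (the same adjusted over the list alone; adjusted p = 3.31e-23, and adjusted p = 0.200 with an estimated correlation). GADD45A (1.16, SE 0.07) rose beside CDKN1A and MDM2. Integrated stress response genes had 20 higher and 2 lower of 31 (20 and 4 adjusted over the list alone; adjusted p = 3.99e-07, and adjusted p = 0.392 with an estimated correlation). CHAC1 (1.56, SE 0.06) and TRIB3 (1.13, SE 0.08) rose. Actomyosin and fibroblast activation genes had 21 higher and 4 lower of 29 (the same adjusted over the list alone; adjusted p = 2.67e-05, and adjusted p = 0.414 with an estimated correlation). ACTA2, the smooth muscle actin of myofibroblasts, rose by 1.37 (SE 0.07), while the growth factor receptor gene PDGFRA fell (−1.48, SE 0.06). Lung fibroblast markers had 3 higher and 7 lower of 13 (the same adjusted over the list alone; adjusted p = 7.92e-04, and adjusted p = 0.392 with an estimated correlation). DCN (−1.53, SE 0.07) and TCF21 (−1.72, SE 0.07) fell. Interferon-stimulated genes had 2 higher and 21 lower of 33 (3 and 22 adjusted over the list alone; adjusted p = 0.00198, and adjusted p = 0.392 with an estimated correlation). IFIT1 (−1.96, SE 0.09) and IFITM1 (−1.55, SE 0.14) fell. Ribosomal protein genes had 2 higher and 51 lower of 86 (2 and 52 adjusted over the list alone; adjusted p = 5.27e-06, and adjusted p = 0.599 with an estimated correlation). Their median was −0.26, and RPS3 was at −1.64 (SE 0.06). Epithelial markers had 2 higher and 0 lower of 5 (the same adjusted over the list alone; adjusted p = 0.0177, and adjusted p = 0.435 with an estimated correlation). KRT18, a keratin gene, rose by 1.60 (SE 0.09). Extracellular matrix genes moved both ways, 23 higher and 16 lower of 50, the same adjusted over the list alone, without a list call by camera (adjusted p = 0.209). FN1, encoding fibronectin, rose by 1.24 (SE 0.07).

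In all, 6074 of 14806 genes tested changed in WI38 siORCA, 2940 higher and 3134 lower, of which 321 and 872 changed at least 2-fold. The split was 2329 and 3646 with library totals, 3122 and 3001 with DESeq2 size factors and 2346 and 2000 with DESeq2, so which direction held more genes depended on the scaling and the method. Without siORCA replicate 1, 2087 genes were called.

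In U2OS siEZH2, MMP3, encoding the matrix protease stromelysin, rose from 1.01 ± 0.151 to 381 ± 22.5 CPM (log2 fold change 8.55, SE 0.11, adjusted p = 3.44e-08). HMGCS1, an enzyme of the mevalonate pathway, rose from 80.8 ± 4.74 to 2035 ± 54.3 (4.66, SE 0.08), and TNC, encoding tenascin C, from 243 ± 10.2 to 2017 ± 33.3 (3.06, SE 0.07). PHGDH, the first enzyme of serine synthesis, fell from 184 ± 9.06 to 23.1 ± 0.216 (−3.00, SE 0.06, adjusted p = 6.68e-08), and the proliferation marker MKI67 from 960 ± 36.9 to 322 ± 18.1 (−1.57, SE 0.06). Other large increases were in SULT1B1 (8.55, SE 0.14), COL19A1 (8.32, SE 0.18), KRTAP2-3 (7.16, SE 0.11, one of several near-identical keratin-associated genes) and the receptor gene IL1RL1 (7.11, SE 0.45). Large decreases were in the hormone gene FGF21 (−7.60, SE 0.41), the kinase gene MAP2K6 (−7.50, SE 0.39) and the troponin genes TNNT2 (−6.99, SE 0.29) and TNNC1 (−6.30, SE 0.16).

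G2/M mitotic genes in U2OS siEZH2 had 0 higher, 56 lower and 1 that did not pass (the same adjusted over the list alone; adjusted p = 1.76e-22, and adjusted p = 0.568 with an estimated correlation), with CENPF (−1.49, SE 0.06), ECT2 (−1.54, SE 0.05) and NDC80 (−1.60, SE 0.07). Replication-dependent histones had 0 higher and 38 lower of 45 (0 and 41 adjusted over the list alone; adjusted p = 1.13e-14, and adjusted p = 0.568 with an estimated correlation), with H2BC7 (−2.48, SE 0.07) and H4C1 (−2.53, SE 0.09). Integrated stress response genes had 2 higher and 27 lower of 32 (2 and 28 adjusted over the list alone; adjusted p = 6.14e-20, and adjusted p = 0.568 with an estimated correlation), with PSAT1 (−2.50, SE 0.06) and the cystine transporter gene SLC7A11 (−2.62, SE 0.06). Cholesterol biosynthesis had 17 higher and 5 lower of 26 (the same adjusted over the list alone; adjusted p = 1.34e-08, and adjusted p = 0.568 with an estimated correlation), with HMGCS1 and FASN (1.41, SE 0.06) higher. G1/S E2F targets had 3 higher and 26 lower of 33 (adjusted p = 4.50e-06, and adjusted p = 0.568 with an estimated correlation), with FANCD2 (−2.23, SE 0.07). Replication fork genes had 3 higher and 28 lower of 38 (3 and 29 adjusted over the list alone; adjusted p = 7.82e-05, and adjusted p = 0.568 with an estimated correlation), with TYMS (−1.41, SE 0.06). Licensing genes had 4 higher and 21 lower of 33 (adjusted p = 0.0103, and adjusted p = 0.568 with an estimated correlation), with MCM2 (−1.95, SE 0.08) and MCM6 (−1.57, SE 0.10), and the cohesin, condensin and CTCF list 3 higher and 21 lower of 27 (adjusted p = 3.67e-04, and adjusted p = 0.568 with an estimated correlation). For the G1/S, licensing and cohesin lists the counts were the same adjusted over the list alone.

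Unfolded protein response chaperones in U2OS siEZH2 had 17 higher and 6 lower of 24 (adjusted p = 0.00121, and adjusted p = 0.583 with an estimated correlation), with HSPA5 (1.16, SE 0.06) and CALR (1.12, SE 0.06). Extracellular matrix genes had 26 higher and 15 lower of 50 (adjusted p = 0.00393, and adjusted p = 0.568 with an estimated correlation), with TNC higher and LOXL4 lower (−4.37, SE 0.08). Osteoblast genes had 5 higher and 2 lower of 9 (adjusted p = 0.0244, and adjusted p = 0.568 with an estimated correlation). ALPL (2.91, SE 0.10) and SPP1 (2.83, SE 0.11) rose, and RUNX2, the transcription factor of the lineage, fell (−1.16, SE 0.06). p53 targets had 20 higher and 7 lower of 33 (adjusted p = 0.0222, and adjusted p = 0.648 with an estimated correlation). The death receptor gene FAS was higher (1.44, SE 0.06) and GDF15 lower (−3.86, SE 0.14). The counts for these 4 lists were the same adjusted over the list alone. Interferon-stimulated genes had 4 higher and 24 lower of 38 (5 and 24 adjusted over the list alone; adjusted p = 0.00311, and adjusted p = 0.583 with an estimated correlation), and STAT2 fell (−1.53, SE 0.06). Inflammatory cytokines and NF-kB targets had 14 higher and 9 lower of 32 (14 and 10 adjusted over the list alone; adjusted p = 0.0244, and adjusted p = 0.568 with an estimated correlation). MMP3 was higher and CCL2 lower (−2.07, SE 0.08). Ribosomal protein genes had 14 higher and 52 lower of 87 (14 and 53 adjusted over the list alone; adjusted p = 0.00122, and adjusted p = 0.767 with an estimated correlation). RPS3 was at −1.12 (SE 0.06). Neural markers had 8 higher and 3 lower of 12 (the same adjusted over the list alone; adjusted p = 0.0274, and adjusted p = 0.568 with an estimated correlation). Epithelial markers had 2 higher and 8 lower of 14 (the same adjusted over the list alone) without a list call by camera (adjusted p = 0.142). ESRP1, a splicing regulator of epithelial cells, fell (−6.16, SE 0.48).

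In all, 14149 of 23189 genes tested changed in U2OS siEZH2, 6530 higher and 7619 lower, of which 2580 and 4063 changed at least 2-fold. The split depended on scaling, with 5277 higher and 9029 lower with library totals and 7050 and 6864 with DESeq2 size factors. The median log2 fold change of all genes was −0.09 with TMM scaling and −0.24 with library totals, and the counts of higher and lower genes include changes smaller than the latter. Each read end was counted separately in these libraries.

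**Figure D2:**
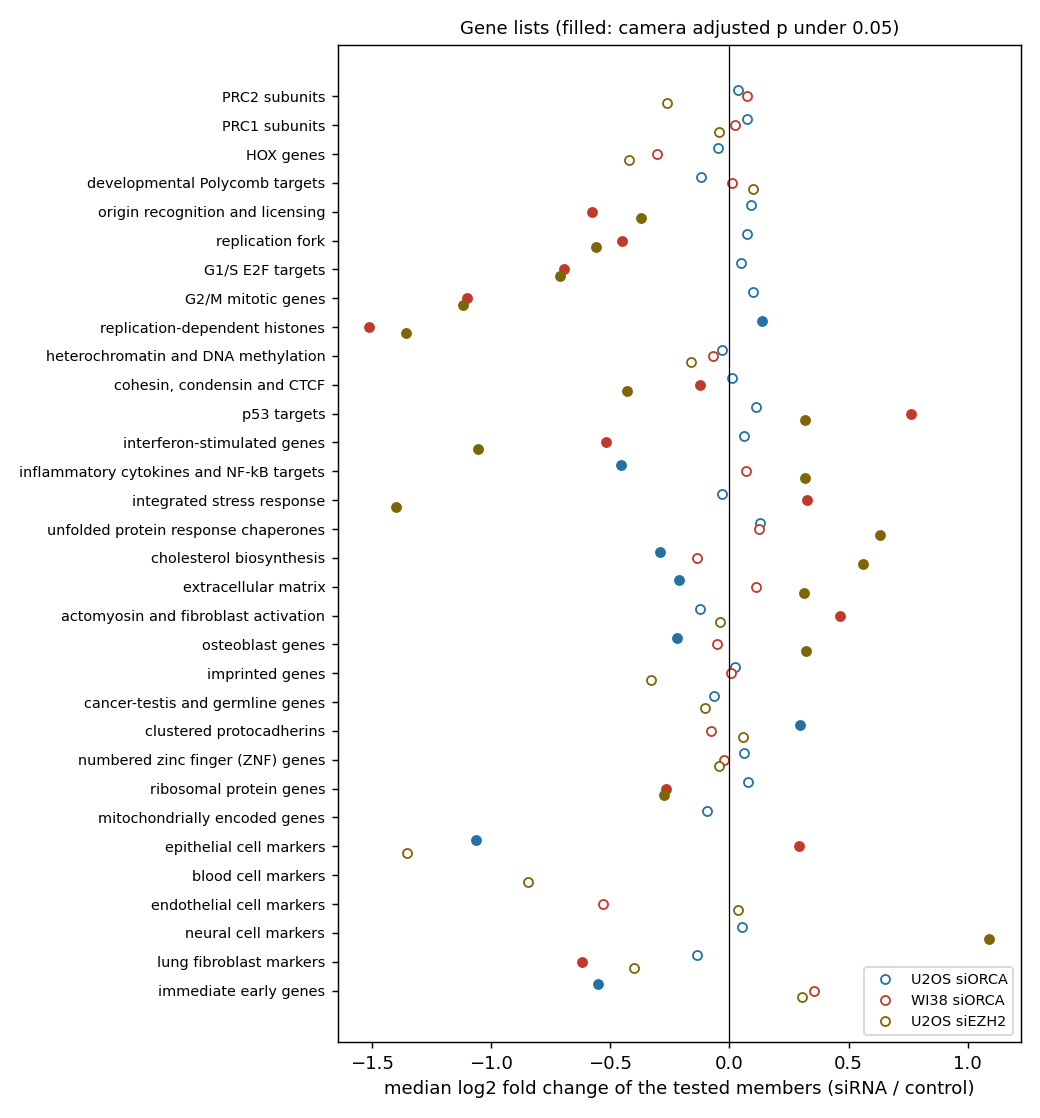
Median log2 fold change (x axis, siRNA over control) of each gene list with at least 5 tested members (y axis). Colours mark U2OS siORCA (blue), WI38 siORCA (red) and U2OS siEZH2 (olive), and medians are over the tested members. Filled points had a camera adjusted p under 0.05 with the preset correlation. None of these calls held with an estimated correlation, a version with few degrees of freedom in 4 libraries. G2/M genes lay at −1.10 in WI38 siORCA, −1.12 in U2OS siEZH2 and 0.10 in U2OS siORCA. Some open points within 0.1 of 0 changed sign under other scalings. In U2OS siORCA these were the cohesin and imprinted lists, and in WI38 siORCA the PRC1, developmental and imprinted lists. In U2OS siEZH2 they were the PRC1, developmental, actomyosin, protocadherin, zinc finger and endothelial lists.

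The Polycomb lists were not called by camera in any of the 3 comparisons. Of 12 PRC2 and 23 PRC1 subunits tested in U2OS siORCA, 0 passed with edgeR, DESeq2 or limma, and 1 and 4 had an unadjusted p under 0.05 with edgeR. Camera gave an adjusted p = 0.847 for PRC2 and an adjusted p = 0.875 for PRC1. Genes with many transcripts, such as EZH2, kept few counts in these libraries, so this does not show that the subunits were unchanged. In WI38 siORCA, 2 PRC2 subunits were higher and 5 lower of 13 (the same adjusted over the list alone; adjusted p = 0.804, with a median of 0.07 and a mean of −0.04), including EZH1, the paralog of EZH2 (−0.57, SE 0.09), and PHF19 (−0.46, SE 0.08). PRC1 subunits there had 3 higher and 2 lower of 23 (3 and 1 adjusted over the list alone; adjusted p = 0.804), and CBX2, which binds the histone mark left by PRC2, fell (−1.26, SE 0.17). In U2OS siEZH2, 4 PRC2 subunits were higher and 8 lower of 14 (the same adjusted over the list alone; adjusted p = 0.389): JARID2 rose (0.90, SE 0.06), and RBBP4 (−1.34, SE 0.05), PHF19 (−0.91, SE 0.07) and EZH1 (−0.88, SE 0.08) fell. PRC1 subunits had 7 higher and 10 lower of 23 (the same adjusted over the list alone; adjusted p = 0.657), with PCGF5 lower (−1.28, SE 0.05). HOX genes had 0 higher and 1 lower of 26 in U2OS siORCA (HOXB9, −0.45, SE 0.11; list adjusted p = 0.875), 2 and 5 of 15 in WI38 siORCA (adjusted p = 0.181), the same adjusted over the list alone, and 7 and 15 of 36 in U2OS siEZH2 (7 and 16 adjusted over the list alone; adjusted p = 0.364). HOXA3 fell in WI38 siORCA (−0.90, SE 0.12) and in U2OS siEZH2 (−3.39, SE 0.14), HOXA5 fell in WI38 siORCA (−1.54, SE 0.09) and HOXC8 rose in U2OS siEZH2 (1.39, SE 0.09). Developmental regulators known as Polycomb targets had 2 higher and 11 lower of 45 in U2OS siORCA (4 and 14 adjusted over the list alone; adjusted p = 0.103), 7 and 8 of 33 in WI38 siORCA (the same adjusted over the list alone; adjusted p = 0.532) and 31 and 20 of 76 in U2OS siEZH2 (32 and 22 adjusted over the list alone; adjusted p = 0.332). Among them, SOX2 was higher and the signalling genes WNT6 (−1.45, SE 0.20) and WNT7A (−1.69, SE 0.30) lower in U2OS siORCA. MEIS2 was higher (0.99, SE 0.07) and BMP4 lower (−1.72, SE 0.07) in WI38 siORCA, and TBX3 was higher (2.68, SE 0.06) and BMP4 lower (−2.18, SE 0.10) in U2OS siEZH2.

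Lists not yet described were not called by camera, and are given as members higher and lower. In U2OS siORCA these were G1/S E2F targets (1 and 0 of 25), p53 targets (0 and 1 of 28), interferon-stimulated genes (2 and 0 of 16) and actomyosin genes (1 and 0 of 25). The same held for imprinted genes (0 and 1 of 14), numbered zinc finger genes (5 and 3 of 338), mitochondrially encoded genes (0 and 1 of 10), neural cell markers (1 and 0 of 8) and lung fibroblast markers (0 and 1 of 8). Camera's adjusted p-values for these lists ran from 0.103 to 0.729, and the counts were the same adjusted over the list alone except for p53 targets (0 and 0), actomyosin genes (0 and 0), numbered zinc finger genes (4 and 3), neural cell markers (3 and 3) and lung fibroblast markers (0 and 2). In the same comparison, 0 members passed with edgeR, DESeq2 or limma for heterochromatin genes (28 tested, 2 with an unadjusted p under 0.05 in edgeR), the cohesin, condensin and CTCF list (24 and 2), unfolded protein response chaperones (23 and 6), cancer-testis genes (12 and 2) and ribosomal protein genes (79 and 10). IFI44L, an interferon-stimulated gene at 3, 9, 38 and 26 counts, rose (2.31, SE 0.44), though not with DESeq2. Lists with fewer than 5 tested members were not tested as lists: blood and endothelial markers had 2 members each, with 1 lower in each.

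In WI38 siORCA, the uncalled lists were heterochromatin and DNA methylation genes (5 and 9 of 32), inflammatory cytokines and NF-kB targets (9 and 8 of 25), unfolded protein response chaperones (9 and 3 of 24), cholesterol biosynthesis (3 and 9 of 26) and osteoblast genes (1 and 3 of 8). They also included imprinted genes (3 and 4 of 18), clustered protocadherins (2 and 2 of 36), numbered zinc finger genes (55 and 63 of 469), endothelial cell markers (1 and 4 of 7) and immediate early genes (13 and 6 of 25). Camera's adjusted p-values for these lists ran from 0.137 to 0.996, and the counts were the same adjusted over the list alone except for heterochromatin and DNA methylation genes (6 and 10), unfolded protein response chaperones (10 and 3), osteoblast genes (2 and 3), clustered protocadherins (0 and 2), numbered zinc finger genes (43 and 45) and immediate early genes (13 and 7). BIRC3, an inhibitor of apoptosis on the NF-kB list, rose (2.76, SE 0.18), and LMNB1, encoding lamin B1, on the heterochromatin list, fell (−1.11, SE 0.09). Not tested as lists were cancer-testis genes (1 lower of 3), blood markers (1 higher of 2) and neural markers (2 lower of 3). In U2OS siEZH2, heterochromatin and DNA methylation genes (10 and 14 of 32), actomyosin genes (13 and 14 of 29), imprinted genes (6 and 9 of 20), cancer-testis and germline genes (14 and 13 of 39) and clustered protocadherins (10 and 14 of 53) were not called. Nor were numbered zinc finger genes (127 and 164 of 483), blood cell markers (2 and 5 of 12), endothelial cell markers (5 and 3 of 12), lung fibroblast markers (3 and 5 of 13) and immediate early genes (14 and 6 of 26). Camera's adjusted p-values for these lists ran from 0.0920 to 0.996, and the counts were the same adjusted over the list alone except for clustered protocadherins (9 and 13). RTL1, an imprinted gene, rose (6.78, SE 0.36). Mitochondrially encoded genes were not analysed in WI38 and U2OS batch 2. Median, mean and camera direction differed in sign for PRC1, HOX, heterochromatin and imprinted genes in U2OS siORCA. They also differed for PRC2, PRC1, developmental, NF-kB, imprinted, zinc finger and immediate early genes in WI38 siORCA, and for actomyosin, imprinted, cancer-testis and endothelial lists in U2OS siEZH2. Under other scalings the median changed sign for cohesin and imprinted genes in U2OS siORCA and for PRC1, developmental and imprinted genes in WI38 siORCA. In U2OS siEZH2 it did so for the PRC1, developmental, actomyosin, protocadherin, zinc finger and endothelial lists.

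The siORCA effect differed between U2OS and WI38 for 1611 of 15824 genes (edgeR interaction test). Of the 1611, 672 were more positive in U2OS and 939 more positive in WI38. With library totals the split was 866 and 698. The count filter of this test ran over all libraries together, and 9767 genes passed the filter in each line alone. The remaining genes had few counts in at least 1 line, so their differences are imprecise. CLDN1 fell in U2OS and rose in WI38 (−2.56, SE 0.17, against 2.27, SE 0.11; adjusted p of the difference = 2.38e-19), as did EDN1 (−1.82, SE 0.15, against 1.89, SE 0.18; adjusted p = 1.58e-14). ID3, an inhibitor of differentiation factors, rose in U2OS and fell in WI38 (1.43, SE 0.32, against −2.12, SE 0.08; adjusted p = 8.24e-11). The p53 target list had a median difference of −0.78, and its call held with an estimated correlation (adjusted p = 5.40e-12 with the preset correlation and adjusted p = 0.0336 with an estimated correlation). G2/M genes had a median difference of 1.07 (adjusted p = 3.02e-27, and adjusted p = 0.108 with an estimated correlation) and histones of 1.56 (adjusted p = 1.35e-37, and adjusted p = 0.0942 with an estimated correlation). Cell line and method of counting go together here and cannot be told apart.

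In U2OS, the siORCA effect differed from the siEZH2 effect for 5207 of 18341 genes (edgeR interaction test), 2754 more positive with siORCA and 2453 with siEZH2. The split was 3400 and 1924 with library totals, 2595 and 2679 with DESeq2 size factors, 2732 and 2857 with DESeq2, 2259 and 2452 without batch 2 control replicate 2 and 2472 and 2775 without siEZH2 replicate a, so neither direction held more genes in all settings. SOX2 rose with siORCA and fell with siEZH2 (1.25, SE 0.12, against −2.21, SE 0.17; adjusted p of the difference = 6.72e-10), and so did DDIT4 (1.02, SE 0.10, against −2.15, SE 0.06; adjusted p = 1.37e-12). MUC4 (−2.86 and −3.34) and CLDN1 (−2.56 and −2.69) fell in both without a called difference (adjusted p = 0.361 and 0.773). This does not show that they were equal. The MUC4 difference of 0.46 became 1.04 (adjusted p = 0.0176) without siORCA replicate 1 and −0.40 (adjusted p = 0.514) without siORCA replicate 2. Only 11149 genes passed the count filter in each experiment alone, and differences of the remaining genes rest on few counts in at least 1 experiment. Batch and method of counting differ between the siORCA and siEZH2 experiments and cannot be told apart from the siRNA.

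Overlaps of called genes were counted in each pair of comparisons, which share no control library. In U2OS and WI38 siORCA, 152 genes were called in the same direction against 110.3 for independent lists, and 165 in opposite directions against 113.6, of 9767 genes tested in both. RGCC, a regulator of the cell cycle (−1.96, SE 0.17, and −2.01, SE 0.07), and TNFRSF11B (−1.52 and −1.13) fell in both lines, and DDIT4 rose in both (1.02 and 0.62). In siORCA and siEZH2 in U2OS, 333 genes were called in the same direction against 258.9 and 224 in opposite directions against 250.0, of 11149; F13A1, MUC4, CLDN1 and CAVIN2 fell and ID3, SGK1 and CA12 rose in both. In WI38 siORCA and U2OS siEZH2, 3233 were called in the same direction against 2042.6 and 1181 in opposite directions against 2041.4, of 14325. SERPINB7 (3.25 and 2.93), RGS4 (2.05 and 3.90) and the protease gene ADAM19 (1.96 and 2.14) rose in both, and SMOC1 (−3.40 and −2.54), the sterol transporter gene ABCG1 (−3.10 and −2.08) and CCL2 (−2.12 and −2.07) fell in both. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was −0.0287 (Spearman's rho 0.00426), 0.108 (0.0619) and 0.281 (0.325) for the 3 pairs. With DESeq2 the same-direction counts of the first 2 pairs fell to 46 and 145.

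**Figure D3:**
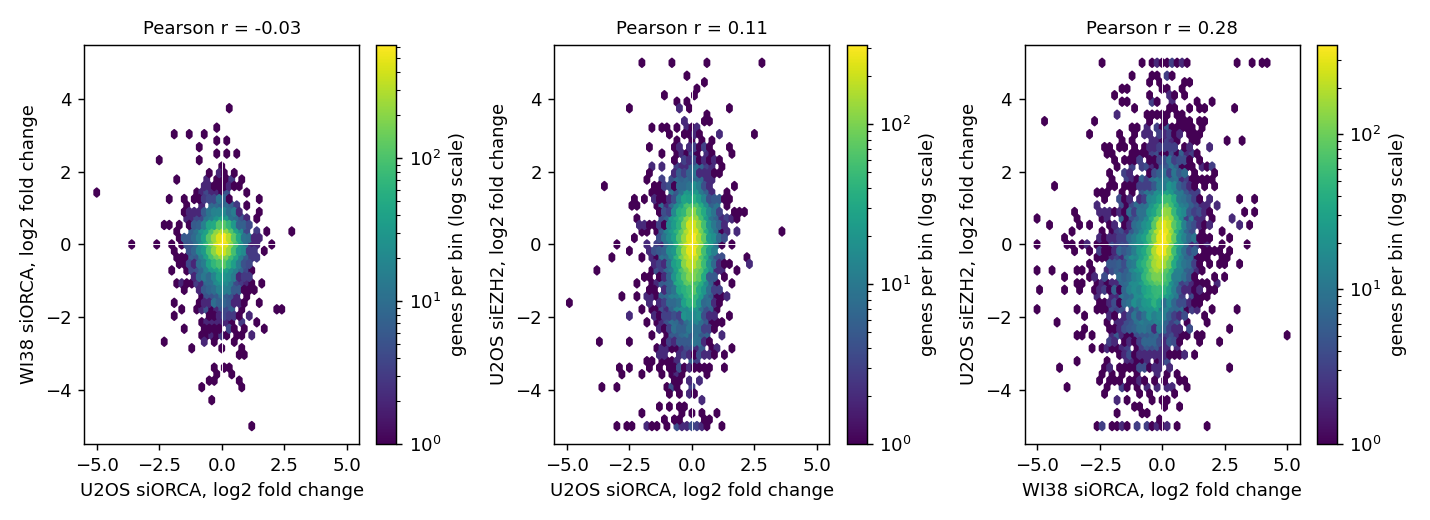
Log2 fold changes (siRNA over control) of genes tested in both comparisons of each pair, as hexagonal bins coloured by the number of genes on a log scale; values beyond 5 in either direction are drawn at the edge. Pearson's r was −0.0287 for U2OS and WI38 siORCA (left), 0.108 for siORCA and siEZH2 in U2OS (middle) and 0.281 for WI38 siORCA and U2OS siEZH2 (right).

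Log2 fold changes of neighbouring genes that do not overlap were compared with 1000 shuffles of gene order within chromosomes. Spearman's rho of consecutive genes was 0.0364 in U2OS siORCA (shuffled mean 0.001, SD 0.0102, highest 0.0382; permutation p = 0.002, adjusted 0.002), 0.1247 in WI38 siORCA and 0.1448 in U2OS siEZH2. For neighbours at least 10 kb apart the U2OS siORCA value was 0.0244 (permutation p = 0.041). For WI38 siORCA and U2OS siEZH2 the permutation p = 0.001 (adjusted 0.0015), the smallest that the shuffles can give; these are relations across genes, which are not independent replicates. Of 138 tests of called genes per chromosome (Fisher's exact test, 2-sided), 6 had an adjusted p under 0.05. These tests treat genes as independent, though neighbours were related, so their p-values may be too small. They were not repeated without histones or other clustered families. In WI38 siORCA, genes on chromosome 12 were more often higher (24.7% of 757 against 19.9% of all; adjusted p = 0.0243) and those on chromosome 9 less often (15%; adjusted p = 0.0370). Genes on chromosome 6, which holds the main histone clusters, were more often lower (27.6% of 811 against 21.2%; adjusted p = 0.00105), and those on chromosome 19 were less often higher (15.3%; adjusted p = 0.00838) and less often lower (16.9%; adjusted p = 0.0186). In U2OS siEZH2, genes on chromosome 1 were more often higher (31.6% of 2259 against 28.2%; adjusted p = 0.00838).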

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

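The tests of LRWD1 transcripts, of the relation between lines and of RNA without a poly(A) tail were chosen after the results were seen. The halved and thinned counts and the windows along chromosomes were added after the data were examined, with their outcome still unknown.

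The siORCA effect differed between U2OS and WI38 for 1611 genes by edgeR's interaction test. It covered 15824 genes, while 9767 passed the count filter in each line alone, so some differences rest on few counts in 1 line. The values that follow are differences in log2 fold change, U2OS minus WI38, for named genes that passed it. Among cell cycle, replication and histone genes, CCNA2 (1.59), CCNB1 (1.40), CDC6 (1.08), CDK2 (0.44), KIF20A (1.62), MCM4 (1.09), MCM7 (1.70), RRM2 (1.03), TOP2A (1.24), H2AC12 (2.51), H2AC15 (1.43) and H4C9 (1.93) were more positive in U2OS. Of p53 and integrated stress response genes, CDKN1A (−1.29), GADD45A (−1.12), MDM2 (−1.05), CHAC1 (−1.26), SLC7A5 (−0.76) and TRIB3 (−1.60) were more positive in WI38. Differences among immediate early, cytokine and sterol genes were found for CCN1 (−2.35), CCN2 (−1.21), DUSP5 (−1.92), LIF (−0.76), CCL2 (1.52), FDPS (−0.67), SQLE (−0.76) and ABCG1 (3.69). Matrix, actomyosin and surface genes that differed were ACTA2 (−1.61), ADAM19 (−1.58), COL6A3 (−1.29), FN1 (−1.59), PDGFRA (1.28), CLDN1 (−4.89), KRT18 (−2.02), CAVIN2 (−1.33), EDN1 (−3.77), OXTR (−3.00), RGS4 (−4.47), GPC5 (3.48), SMOC1 (3.37) and CA12 (1.19). Genes of or responsive to bone morphogenetic protein signalling that differed were ID1 (2.86), ID3 (3.50), ID4 (2.12), ATOH8 (3.10), SMAD6 (1.78), SMAD9 (1.73), BMP4 (0.92) and BMP5 (3.23). Others were ABTB2 (1.91), AGT (3.88), CBX2 (1.35), HOXA5 (1.35), PHF19 (0.68), IFI44L (4.02), SGK1 (2.60), RN7SL1 (2.12), SNORD17 (4.03) and RPS3 (1.51). PCSK2 (5.81) and DIO2 (−6.58) had very few U2OS counts, so their differences are imprecise, and LRWD1 (1.95) rests on U2OS counts that lay on transcripts not classed as protein coding.

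Gene lists differed between the lines by camera on the interaction. These lists include members with too few counts for the test within 1 line. Epithelial markers had 9 members here, 1 of them called, more than in either line alone. Clustered protocadherins had 44, with 0 called, against 25 tested in U2OS siORCA. The median differences of both lists are therefore uncertain. Median differences above 0 were those of origin recognition and licensing (0.67), replication fork (0.45), G1/S E2F targets (0.71), G2/M mitotic genes (1.07), replication-dependent histones (1.56), cohesin and condensin (0.36), clustered protocadherins (0.61) and ribosomal protein genes (0.24). Median differences below 0 were those of p53 targets (−0.78), integrated stress response (−0.55), extracellular matrix (−0.28), actomyosin and fibroblast activation (−0.54), epithelial cell markers (−1.67) and immediate early genes (−0.81). With an estimated correlation the call held for the p53 list (adjusted p = 0.0336) and for none of the others, whose lowest adjusted p was 0.0942.

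LRWD1 was not called lower in U2OS siORCA. Of its counts there, 100% lay on transcripts not classed as protein coding, so the U2OS counts may miss the mature mRNA whatever its level. A knockdown that failed, or libraries with wrong labels, cannot be told apart from this. Pearson's r of the siORCA effects in both lines was −0.0287 across genes, which unlike responses of the lines could give as well. The difference between the lines stays open as a biological explanation and was not tested.

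Histone transcripts fell in WI38 siORCA, and a lower yield of RNA without a poly(A) tail is a candidate explanation. The median of 5 RNA polymerase III transcripts was −1.79 there, as this explanation predicts. A lower production of these transcripts would give the same value, so it does not decide the question. All samples were depleted of ribosomal RNA in the same way, and the steps given in the labels' protocols, as listed above, include no selection on that tail. In U2OS siEZH2, histones fell while the same 5 RNA polymerase III transcripts had a median of −0.0392 and none lay under −0.21. They were not flat, as RN7SL3 rose by 2.46 and RN7SL1 by 0.62, with RN7SK at −0.14, RMRP at −0.04 and RPPH1 at −0.21. None fell as the histones did, which argues against a lower yield there. In U2OS siORCA, where 4 histones rose, only 2 of these transcripts were tested. RN7SL3 rose by 0.86 and RN7SL1 was at 0.11 and did not pass. A yield that differed between libraries therefore stays open for the U2OS histones, and for the histone difference between the lines. Loss of ORCA, fewer dividing cells and a lower technical yield all stay open for the WI38 histones.

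Most genes tested were called in U2OS siEZH2. Counting both read ends could raise the number of calls, but 14011 genes were called with halved counts, and unequal depth could too, but 13557 were called with all libraries thinned to the smallest total. Both argue against these as the main cause. Libraries from subclones or lines that differ in copy number were looked for in windows of 50 genes. Of 453 windows, 4.42% had a median beyond 0.5 (exact 95% interval 2.72% to 6.74%). The bounds set beforehand were over 20% of windows if this was the cause and under 5% if not. The share was far below the first bound, but its interval includes the second, so this explanation stays open. The effect of losing EZH2 was not tested against it, and this cannot be told apart here.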

How the results depend on the processing

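The settings without rRNA genes, with genes of 1 transcript, with halved counts and with thinned counts were chosen after the data were examined. In U2OS siORCA, the 827 changed genes of 14014 became 350 with DESeq2, 255 at 2-fold or more and 470 at an adjusted p under 0.01. Among 3394 genes with 1 annotated transcript, 299 changed. The last 3 counts are lower because fewer genes can pass. Of the calls among genes with 1 annotated transcript, 41.8% were higher, against 32.65% in the main fit, so the balance of directions moved too. Leaving out 1 library gave 280 to 769, with 444 without control replicate 1 and 280 without control replicate 2. In WI38 siORCA, 6074 became 1193 at 2-fold or more and 2087 to 6521 without 1 library, the lowest without siORCA replicate 1. In U2OS siEZH2, 14149 became 6643 at 2-fold or more and 11019 to 15391 without 1 library. The lone library left in a group was assumed to vary like the others. Called lists fell from 8, 13 and 16 to 0 with an estimated correlation, and fry called 0, 17 and 23. The estimated correlation has few degrees of freedom in 4 libraries, so the fall does not by itself show that correlation between members caused it. Where the estimate was high, as for osteoblast genes in U2OS siORCA (0.397), it may have contributed. EZH2 in WI38 siORCA was −0.71 to −0.56 without 1 library. RMRP in U2OS siEZH2 (−0.04) was 0.0414 with DESeq2 size factors and with DESeq2, and −0.11 to 0.14 without 1 library. Without 1 library, ID4 in U2OS siORCA (0.06) was −0.0239 to 0.17 and ID2 in U2OS siEZH2 (0.04) was −0.0527 to 0.19, and with library totals ID2 was −0.11. The differences between siORCA and siEZH2 effects were −0.40 to 1.04 for MUC4 and −0.10 to 0.22 for CLDN1 without 1 library. Same-direction overlaps of 152 and 333 became 46 and 145 with DESeq2. Apart from those with a stated reason, the cause was not tested.

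With the replicate number as a block, 1249 genes changed in U2OS siORCA, 474 higher and 775 lower, 6266 in WI38 siORCA, and 1644 differed between the lines. Deviations of same-numbered libraries correlated at 0.117 in U2OS and 0.0837 in WI38, and with 2 pairs the numbers are not shown to pair the libraries. For U2OS siEZH2, no paired analysis was possible because the columns of its table carry no certain replicate numbers. Of 201 named values, 26 changed call or direction in any setting. Of simulated changes of 1 on the log2 scale, 53.2% were recovered in U2OS siORCA, 86.6% in WI38 siORCA and 46.3% in U2OS siEZH2. Far fewer genes were changed in the simulations than were called in the data, so these shares do not estimate what was missed there.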

Other observations

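Genes that respond to bone morphogenetic protein signalling were chosen for this paragraph after their values were seen, and were not tested as a list. In WI38 siORCA, ID1 (−2.33), ID2 (−1.13), ID3 (−2.12), ID4 (−2.12), ATOH8 (−1.59), SMAD6 (−1.10) and SMAD9 (−1.62) fell. In U2OS siORCA, ATOH8 (1.55) and ID3 (1.43) rose, though neither did with DESeq2, and SMAD6 (0.74) rose. ID1 (0.58), ID4 (0.06) and SMAD9 (0.17) did not pass there, and ID2 was not tested. In U2OS siEZH2, ID1 (2.58), ID3 (2.74) and ID4 (2.45) rose, SMAD6 (−0.69) fell, and ATOH8 (0.64), ID2 (0.04) and SMAD9 (0.25) did not pass.

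RPS3 fell by 1.64 in WI38 siORCA while the ribosomal protein list had a median of −0.26. In U2OS siEZH2, HMGCS1 rose by 4.66 while the cholesterol biosynthesis list had a median of 0.56.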
